A study of Rattus norvegicus with 2 samples.

How the data were processed

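Total liver RNA of 6 rats per group was pooled, labelled with Cy3 and hybridised to 1 Agilent one-colour array per pool, per the labels' protocols, which also state an RNA integrity number above 8.5 for the samples pooled. The group treated with a compound abbreviated EEP is called the propolis group here, since the series title speaks of propolis extracts, and the other group is called the saline group. Scanned images were read with Agilent Feature Extraction 9.5, per the submitters' processing notes.

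The authors deposited log2 values for 41012 probes on both arrays, with a letter P, M or A per probe and array and a linear fold ratio between the arrays. The values appeared to be quantile normalized by the authors, since the sorted columns differed by at most 0.0255 log2 units and both had a median of 5.07; the rest of the normalization, the background correction and the meaning of the letters are not given in the sources used here. P was taken here as detected. The deposited fold ratio equals 2 to the power of the propolis value minus the saline value within 1.84e-07 log2 units, which fixes its direction. The series matrix deposited by the authors holds the same log2 values rounded (largest gap 0.005) for the 23054 probes with P on both arrays, with column medians of 7.53 for the propolis and 7.52 for the saline array, so its scale and direction are known and it is uncentred.

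The design fixed before the data were examined expected scanner signals, to be scaled to the 75th percentile of each array. The deposited values were already normalized log2 values, with the same 75th percentile of 7.94 on both arrays, so that this step moved no difference. Signals are printed as deposited, in log2 units. No saturation marks or control spots were marked in the files, so the planned exclusion of saturated probes could not be applied to values that ranged from 1.72 to 18.6.

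Gene symbols came from the deposited table and were updated by Entrez gene ID to the RefSeq names of the rat assembly GRCr8, of which only names and gene order were used. Of 21871 probes with a symbol, 20959 matched and 912 kept the file's symbol, and 4616 took a different current symbol; 19141 probes had no symbol and were counted, not named. Symbols after updating numbered 17108. Each gene was read by its brightest probe (highest mean of both arrays), and 11915 genes with a P on at least 1 array entered the comparison, 933 of them with P on 1 array only over all their probes. For such genes the fold is a bound: the bright value against the higher of the dim probe's own value and the lowest P value of the dim array (3.83 on both arrays).

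With 1 array per group there is no residual variation, and no p-value was computed. Genes were counted at a rule of size, at least 2-fold. Each of 48 gene lists fixed before the data were examined, covering pathways, handling, sex bias and cell types, was described by the percentile of its median among 10000 random lists of the same size matched on mean signal in 20 bins; a list with at least 5 measured members stood apart when this percentile was under 2.5 or over 97.5. That percentile describes these 2 arrays and not the treatments. Lists overlap, and 2 lists with 4 measured members each were not scored. On simulated data, made by shuffling the differences of the 11915 genes within signal bins, 11 of 200 lists of 25 genes with no shift stood apart (5.5%), as did 94% of 50 lists shifted by 0.3 log2 units and 100% of 50 lists shifted by 0.5. The random lists and this shuffling both treat genes singly, so neither holds the joint variation of genes in a real list.

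Genes were named by a rule fixed in the same way: the 12 highest and 12 lowest among genes with P on both arrays whose detected probes all lay on the same side of 0; for each list that stood apart up to 4 members furthest in its direction, and for other lists up to 3 furthest from 0; a set of genes of alcohol, lipid, inflammatory and antioxidant metabolism; and the 5 largest bounds in each direction. Names outside it are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

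Alternatives were centring on the median of each array, quantile normalization, loess centring on signal (span 0.3), the series matrix values, P on both arrays, no filter, the mean of a gene's probes, the probe with the median difference, thresholds of 1.5-fold and 3-fold, 50 signal units added to values taken out of the log, unmatched random lists and the mean of a list. For a gene with an even number of probes, the median probe was the lower of the middle pair, so this alternative leans towards lower differences. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The number of arrays limits the precision of every value.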

Results

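Liver RNA was compared between male Wistar rats of 22 weeks of age that had received a propolis extract and rats that had received saline, both after an alcohol feeding period meant to produce a fatty liver. Alcohol at 52% had been given at 1% of body weight for 7 weeks, and the propolis extract in a 50% ethanol solution, or normal saline, then followed at 0.1% of body weight for 4 weeks. RNA of 6 animals per group was pooled, and each pool was hybridised to 1 one-colour Agilent array, so that the comparison rests on 2 arrays and has no replicate check. The question is which liver transcripts differed in level between the treatments, and every difference below is the log2 signal of the propolis pool minus that of the saline pool. Of 41012 probes, 24380 (59.4%) carried the detection letter P on the propolis array and 24344 (59.4%) on the saline array, and 23054 carried it on both.

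Genes of drug metabolism, conjugation, fatty acid oxidation and cholesterol synthesis were mostly higher in the propolis pool than in the saline pool. Acute phase, interferon response, cell cycle, macrophage, erythroid, T and NK cell and platelet genes were lower, and so were the stearoyl-CoA desaturase gene Scd and the fatty acid synthase gene Fasn, while other genes of fatty acid synthesis lay on either side of 0. Among 11915 genes with a detected probe on at least 1 array, 427 were at least 2-fold higher and 607 at least 2-fold lower in the propolis pool, while 9734 genes (81.7%) differed by less than 1.5-fold. Part of this count came from genes detected on 1 array only: among genes detected on both, 192 were at least 2-fold higher and 298 at least 2-fold lower, and with the others at the bound defined below the counts were 304 and 434. Of all genes at least 2-fold apart, 92.4% rested on 1 detected probe, with no other detected probe to check them. Of 46 gene lists that could be scored, 8 had a median above and 16 a median below those of nearly all random lists matched on signal. Chance alone would give 2.3 of 46 if lists were independent and the genes within a list varied independently. Where genes of a list vary together, an ordinary difference between the pools could set more lists apart, and the random lists do not allow for that.

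Signals of the 2 arrays had a Pearson correlation of 0.981 across all probes, which are not independent replicates. A technical spread could be had from the 2596 genes with at least 2 probes detected on both arrays, where the difference read by the brightest probe was set against that of the next. The robust SD of the difference per probe was 0.16 log2 units over all these genes, 0.31 where the mean signal was under 6 and 0.10 where it was 12 or more. Of 54 such genes that were at least 2-fold apart by the brightest probe, 42 (77.8%, exact 95% confidence interval 64.4 to 88.0%) had a second probe on the same side of 0, and 26 had a second probe that was also at least 2-fold apart. Over all 2596 genes the share on the same side was 70.2%, which lies within that interval. These values cover probe and spot error on the same 2 arrays and leave out the spread between animals or pools.

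**Figure D1:**
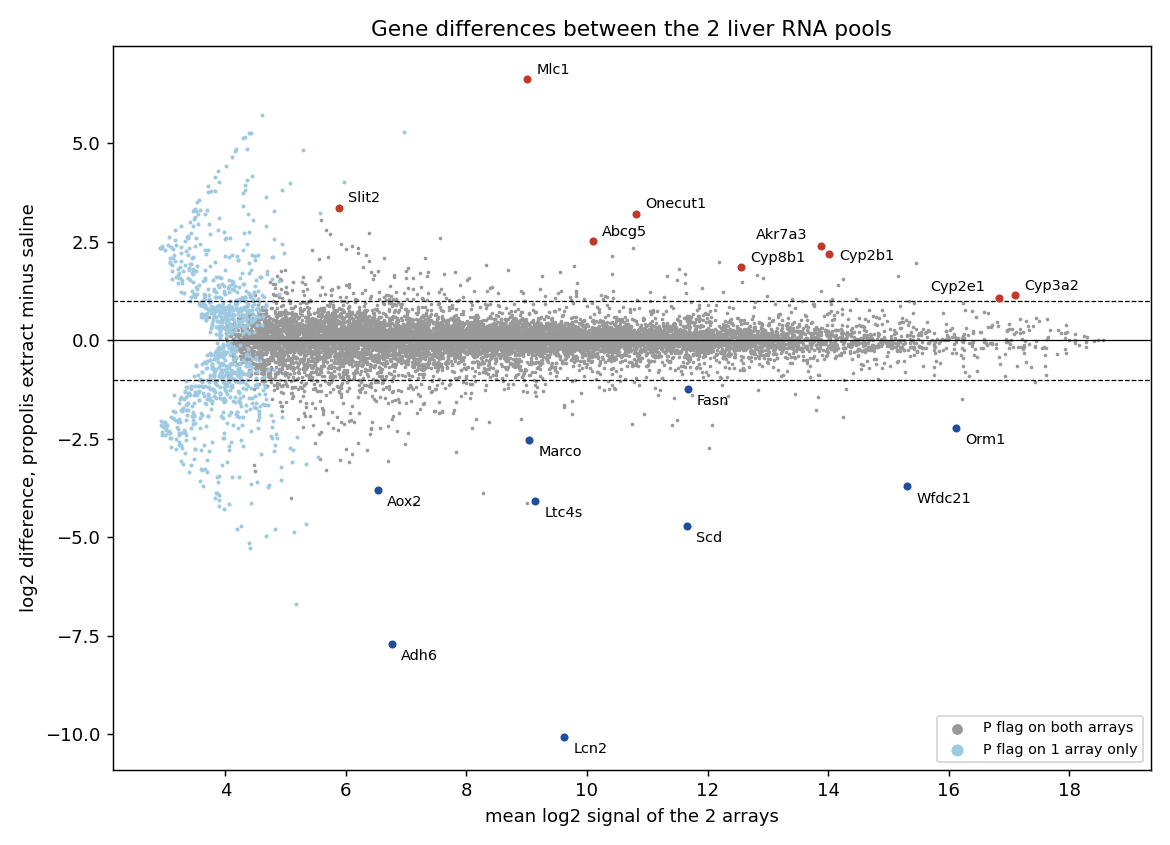
Each point is 1 gene, with the mean log2 signal of the 2 arrays on the x axis and the log2 difference, propolis extract minus saline, on the y axis; grey points had the detection letter P on both arrays, light blue points on 1 array only, and dashed lines mark 2-fold. Named genes higher in the propolis pool are red and lower ones dark blue, with Mlc1 at 6.62 and Lcn2 at -10.07 at the far ends, and the light blue points fan out at low signal.

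Among genes detected on both arrays, Lcn2, which encodes lipocalin 2, a siderophore-binding protein induced in inflammation, was the lowest in the propolis pool, at a log2 signal of 4.59 against 14.66 in the saline pool (log2 difference -10.07, 1071-fold lower). Scd, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, was 26.3-fold lower (9.31 against 14.02). Ltc4s, the leukotriene C4 synthase, was 16.9-fold lower, and Wfdc21, a whey acidic protein family member, 13.1-fold lower at a high signal (13.46 against 17.17). The aldehyde oxidase gene Aox2 had a log2 difference of -3.81, the aldo-keto reductase gene AKR1C3l1 of -4.13 and RGD1560493, a gene without an assigned function in the file, of -4.17. The calcium channel gene Trpv6 (-3.30), the transcription factor gene Etv4 (-3.09), the Wnt receptor gene Fzd2 (-3.06), Dnajc27 (-3.01) and Racgap1 (-2.88) completed the 12 lowest genes. Each of these 12 genes was read by a single detected probe, so that no second detected probe could check it. The propolis signal of Lcn2 (4.59) lay near the lowest detected value of that array (3.83), so the size of its fold is uncertain. The same holds for Trpv6 (4.02), Dnajc27 (4.07), Etv4 (4.51), Aox2 (4.63) and Racgap1 (4.66). Etv4, with 2 probes on the array, and Dnajc27 and Racgap1, with 3 each, had other probes that were detected on neither array. In the deposited coordinates, whose genome build is not given in the sources used here, the Lcn2 probe lies on chromosome 3 from 11511592 to 11511651 and the Scd probe on chromosome 1 from 249459057 to 249459116.

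At the other end, Mlc1, a membrane protein gene best known from astrocytes, was 98.6-fold higher in the propolis pool (log2 signal 12.32 against 5.70), and by its second probe, detected on the propolis array only, at least 32.2-fold higher. The Mlc1 probe lies on chromosome 7 from 127265517 to 127265576 in the same coordinates. Slit2, a secreted guidance protein gene, was 10.3-fold higher by its brightest probe (3.36) and 0.73 log2 units higher by its other probe. Onecut1, which encodes the liver transcription factor HNF-6, was 9.25-fold higher (12.42 against 9.21). The potassium channel gene Kcnj14 (3.05), the kinesin gene Kif11 (2.80), the NADPH oxidase gene Nox4 (2.73), the methyltransferase gene Inmt (2.71), the sterol exporter gene Abcg5 (2.51) and the aflatoxin aldehyde reductase gene Akr7a3 (2.40) were higher as well. A second Kif11 probe was detected on neither array. Saline signals of Kcnj14 (4.06), Slit2 (4.21) and Kif11 (4.26) lay near the lowest detected value of that array (3.83), so the sizes of their differences are uncertain. RGD1564406 (2.69), Spmip11 (2.60) and Mphosph9 (2.43, with a second probe at 0.22) completed the 12 highest genes.

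Genes detected on 1 array only have a bound in place of a fold, formed against the higher of the dim probe's own value and the lowest detected value of the dim array. By that bound Adh6, an alcohol dehydrogenase, was at least 111-fold lower in the propolis pool, followed by Cbln4 at least 25.8-fold, Matn4 at least 14.4-fold, Fhdc1 at least 13.3-fold and Chsy3 at least 10.5-fold lower. The carboxylesterase gene Ces2e was at least 39.1-fold higher, Ttll6 at least 14.6-fold, LOC294497 at least 12.4-fold and the olfactory receptor gene Or52u1 at least 9.42-fold higher.

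Genes of fat burning were higher in the propolis pool, and genes of fat synthesis went both ways, with a few far lower. Of 35 measured members of the fatty acid oxidation and ketogenesis list, 30 lay above 0 and 6 were at least 2-fold higher, with none at least 2-fold lower. The median difference was 0.34, at percentile 100 among 10000 random lists matched on signal. The thioesterase gene Acot1 (1.73), Pdk4 (1.59), which restrains pyruvate oxidation, the enoyl-CoA isomerase gene Eci1 (1.55) and the pantetheinase gene Vnn1 (1.52) had the largest differences, while Cpt1a, the carnitine palmitoyltransferase of fatty acid entry into mitochondria, differed by 0.42 and the regulator Ppara by 0.03. Of 23 measured genes of fatty acid and triglyceride synthesis, 4 were at least 2-fold lower and 1 at least 2-fold higher; the median of -0.10 (percentile 3.85) did not stand apart, although the mean of -0.43 did (percentile 0.14); without Scd and Scd2 the mean was -0.07, within the random range (percentile 26.0). Beside Scd (-4.71), Thrsp, a lipogenic regulator, differed by -1.60, fatty acid synthase Fasn by -1.23 (-1.09 by a second probe) and acetyl-CoA carboxylase Acaca by -0.82 (-0.93 by a second probe). The member at least 2-fold higher, named after its value was seen, was the desaturase gene Fads2 (1.12), and Me1 (0.78), Fads1 (0.76), Elovl2 (0.73) and Elovl6 (0.64), chosen in the same way, lay above 0 too. The probes of Scd2 disagreed, at -3.88 for the brightest and 0.89 for another. Srebf1 and Plin2 had no probe under their symbols.

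Cholesterol synthesis genes were mostly higher. Of 25 measured members, 18 lay above 0, 7 below 0, with a median of 0.38 (percentile 100), and the largest differences were those of the synthase gene Hmgcs1 (1.05, but 0.04 by a second probe), Idi1 (0.89), Hsd17b7 (0.78) and Dhcr7 (0.70), which act along the pathway. The fatty acid transporter gene Cd36 was 2.37-fold higher (9.52 against 8.28), in a list of 24 measured lipoprotein and lipid uptake genes whose median was -0.02 (percentile 42.6) and which also held Apoa2 (0.55) and Lrp1 (-0.52, and -0.32 by a second probe). The lipid droplet list had a median of 0.03 over 13 measured genes (percentile 59.4), with Cidea at 1.10, Abhd5 at 0.64 and G0s2 at -0.36.

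Genes that oxidise, conjugate and export foreign compounds were mostly higher in the propolis pool. The list of glucuronidation, sulfation and efflux genes had a median of 0.57 (0.48 with genes detected on 1 array at their bound), with 18 of 24 measured members above 0, and the cytochrome P450 list a median of 0.40, with 21 of 30 above 0; both lay at percentile 100. The sulfotransferase gene Sult1c2 was 4.37-fold higher (2.13, and 2.63 by a second probe), the glucuronosyltransferase gene Ugt2b1 2.64-fold, the efflux pump gene Abcb1a at least 3.35-fold and Ugt2b7 at least 1.18-fold higher. Cyp2b1, a drug-inducible cytochrome P450, was 4.54-fold higher, and its 4 probes ranged from 0.94 to 2.92. Cyp2j4 (1.66), Cyp2b12 (1.45) and Cyp3a2 (1.13) followed, while Cyp1a2 (0.41, and 0.20 by a second probe) and Cyp1a1 (0.30), targets of the aryl hydrocarbon receptor, differed less. In the cytochrome P450 list 5 members were at least 2-fold higher and 2 at least 2-fold lower, among the latter Cyp2c12 (-1.42). Of its 30 measured members, 9 belong to other lists as well. Probes of such gene families can bind transcripts of close relatives, which these values cannot separate.

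The antioxidant and glutathione conjugation list had a median of 0.25 (percentile 100), with 7 of 38 measured genes at least 2-fold higher and 2 at least 2-fold lower. The glutamate-cysteine ligase subunit gene Gclm was at least 2.44-fold higher, and the aldo-keto reductase genes Akr7a3 (2.40) and Akr1b8 (2.39) and the glutathione transferase gene Gstm3 (1.55) were higher too. Nqo1, a quinone reductase, was 1.81-fold higher (7.98 against 7.13). Catalase, Cat, differed by 0.37, superoxide dismutase Sod1 by 0.16, glutathione peroxidase Gpx1 by -0.17 and heme oxygenase Hmox1 by -0.35. The 2 members at least 2-fold lower, named after their values were seen, were the metallothionein genes Mt2A (3.89-fold lower) and Mt1 (2.83-fold lower), whose products bind metal ions.

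Genes of ethanol metabolism did not stand apart as a list, with a median of 0.17 over 13 measured genes (percentile 97.3), but the microsomal ethanol oxidase Cyp2e1 was 2.09-fold higher (17.37 against 16.30) and the aldehyde dehydrogenase gene Aldh1a1 2.99-fold higher. Alcohol dehydrogenase Adh1, now named Adh1c, differed by 0.28 and the mitochondrial aldehyde dehydrogenase gene Aldh2 by 0.04, while Adh6 lay in the opposite direction, as given above. Kept to genes detected on both arrays, which leaves out Adh6, the list's median was 0.22 and stood apart (percentile 99.3), while the mean of all its members, Adh6 included at its measured difference, was -0.37 and stood apart on the lower side (percentile 0.76). Without Adh6 that mean was 0.24 (percentile 97.8). The propolis extract was given in ethanol and the saline was not, so that the groups also differed in this.

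Bile acid synthesis and transport genes had a median of 0.22 (percentile 99.9), with 17 of 22 measured members above 0. Besides Abcg5 (2.51), Cyp8b1, the sterol 12-hydroxylase, was 3.60-fold higher, the partner of Abcg5, Abcg8, at least 1.80-fold higher, and the organic anion transporter gene Slco1a4 2.32-fold higher. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.15. Genes that mark hepatocytes around the central vein, where much drug metabolism takes place, were also higher (median 0.31 over 13 genes, percentile 99.8), with Slc1a4 at least 1.71-fold higher, Rhbg at 1.09 and glutamine synthetase Glul at 0.44 (0.13 by a second probe). The pericentral members that belong to no other list had a median of 0.13, within the random range (percentile 81.5). Markers of hepatocytes around the portal vein were lower (median -0.41 over 14 genes, percentile 0), among them Sds (-0.73), Uroc1 (-0.70), Aldh1b1 (-0.67) and Arg1 (-0.60), and the general hepatocyte list differed by a median of -0.01 over 15 genes (percentile 52.8), with Hpx at -0.66, Cps1 at -0.56 and Serpina1 at -0.34. Of the 14 periportal genes 12 belong to other lists as well.

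Acute phase and complement genes were mostly lower in the propolis pool. Of 34 measured members, 30 lay below 0 and 13 were at least 1.5-fold lower, with a median of -0.46 (percentile 0). At least 1.5-fold higher were 2 members, among them the hepcidin gene Hamp (0.73). After Lcn2 came the acid glycoprotein gene Orm1 (15.02 against 17.24, 4.68-fold lower), the kininogen gene Kng1 (2.07-fold lower) and the hepatocyte-secreted Fgl1 (1.97-fold lower). Interferon response genes were lower by a median of -0.57 (26 of 31 below 0, percentile 0), led by Isg15 (-1.23), Oasl2 (-1.22) and Ifitm3 (-1.13), with Oasl at least 1.52-fold lower. Inflammatory cytokine and adhesion genes did not stand apart (median 0.08 over 23 genes, percentile 80.7): interleukin gene Il1b differed by -0.24 (-0.13 by a second probe), the chemokine genes Ccl3 by -1.24 and Cxcl12 by 0.71, Nfkbia by -0.96, and Tnf was detected on neither array. Class II antigen presentation genes had a median of 0.02 over 7 genes (percentile 48.6), with RT1-DMa at -0.92, Ctss at -0.70 and Cd74 at 0.47.

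Extracellular matrix genes were slightly lower, with a median of -0.20 over 29 measured genes, 17 of them below 0 (percentile 0.12). The collagen cross-linking enzyme Lox differed by -1.84 (-0.46 by a second probe), fibromodulin, Fmod, by -1.14 and the protease inhibitor Timp1 by -0.99, and Spp1 was at least 1.31-fold lower. Collagen gene Col1a1 differed by -0.10 by its brightest probe, with its 3 probes reaching down to -1.35, and Tgfb1 by -0.12. Without the filter on detection the list's median was -0.08, within the range of random lists (percentile 4.34).

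Markers of macrophages, erythroid cells, T and NK cells and platelets were lower along with these groups. The Kupffer cell and macrophage list, the resident macrophages of the liver, had a median of -0.56 (15 of 16 genes below 0, percentile 0), with Marco 5.78-fold lower, Itgam 3.27-fold, Csf1r 1.62-fold and Cd163 1.71-fold lower, the last with a second probe at a log2 difference of only -0.11. Erythroid genes were all below 0 (10 of 10, median -0.82 or, with genes detected on 1 array at their bound, -0.70, both at percentile 0), among them Ahsp (-1.79) and Alas2 (-1.12). T and NK cell genes had a median of -0.41 (percentile 0.10), with Lck at -1.48, Gzmk at -1.07, Gzmb at -0.94 and Cd3d at -0.88; their mean of -0.36 did not stand apart (percentile 3.19). Platelet genes had a median of -0.55 over 7 genes (percentile 1.35), with Gp1ba at least 7.28-fold lower, Treml1 at -0.99 (0.03 by a second probe), Gp1bb at -0.75 and Pf4 at -0.55. The neutrophil list (median -0.58 over 8 genes, percentile 0.61) held Lcn2, which hepatocytes also make; beside it Mpo was at least 3.40-fold lower, S100a8 3.03-fold and S100a9 2.05-fold lower. Without Lcn2, the only member shared with another list, its median was -0.12 and no longer stood apart (percentile 24.0).

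Other cell types of the liver differed less. Endothelial markers had a median of -0.13 over 17 genes (percentile 5.57), with Cdh5 at -0.68, Lyve1 at -0.63 and Pecam1 at -0.63. Stellate cell and fibroblast markers had a median of -0.10 over 15 genes (percentile 8.59), with Vim at -0.75, Reln at 0.55 and Lrat at 0.48, and cholangiocyte markers of -0.01 over 13 genes (percentile 41.0), with Prom1 at 2.30, Cftr at least 4.80-fold lower and Cldn7 at least 1.03-fold higher. B and plasma cell genes did not stand apart (median 0.11 over 10 genes, percentile 64.5), with Jchain at 0.67, Blk at least 2.15-fold lower and Cd79b at least 2.26-fold higher.

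**Figure D2:**
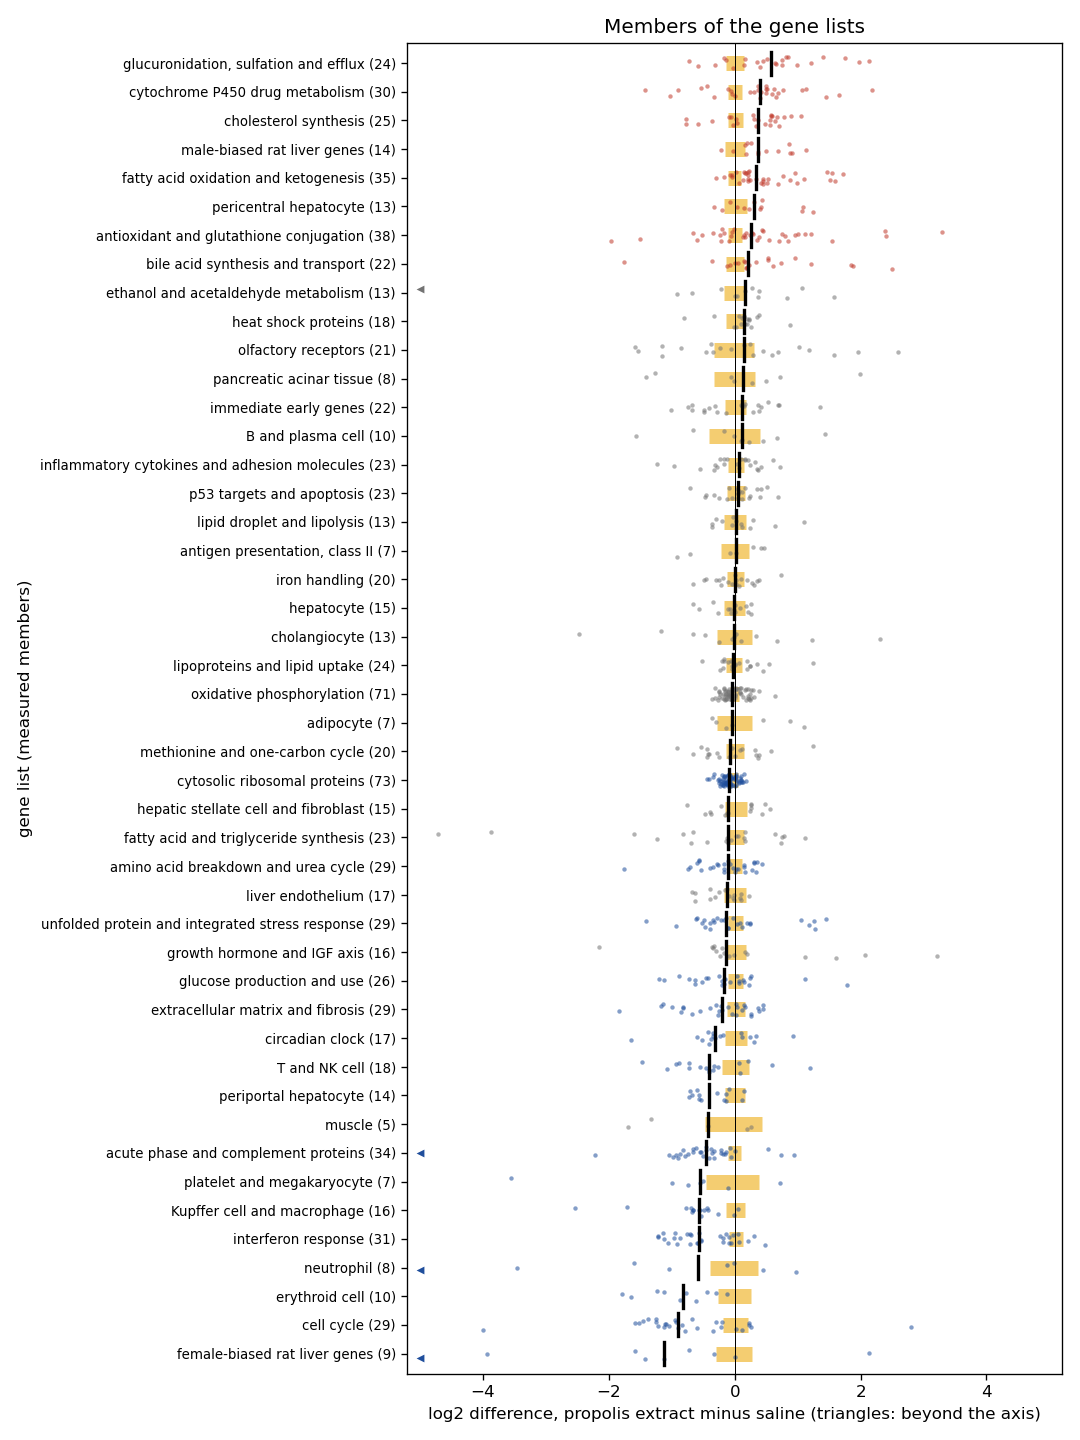
Each row is 1 gene list with the number of measured members, each point 1 member's log2 difference, propolis extract minus saline (x axis), the black bar the list's median and the yellow band the range that holds the central 95% of medians of random lists matched on signal. Lists above the band are red, from glucuronidation at 0.57 to bile acid genes at 0.22, and lists below it blue, down to the female-biased genes at -1.12; triangles stand for members beyond the axis.

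Cell division genes were lower in the propolis pool. Of 29 measured members 23 lay below 0 and 12 were at least 2-fold lower by measured values, or 9 with genes detected on 1 array at their bound. The median was -0.90, or -0.74 at the bound (percentile 0 for both), and 22 members were detected on both arrays. Kif11 (2.80) was the only member at least 2-fold higher. Bub1b was at least 1.67-fold, Melk at least 1.40-fold and Rrm2 at least 1.75-fold lower, and the probes of Top2a disagreed, at least 9.60-fold lower for the brightest, undetected on the propolis array, and at a log2 difference of 0.21 for the one detected on both. With only genes detected on both arrays the median was -0.64 (percentile 0). Cell cycle genes had low signals, where the spread between probes was widest.

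Unfolded protein and stress response genes had a median of -0.13 over 29 genes (percentile 0.77), with Edem1 at -1.41, Sdf2l1 at -0.93, Ddit4 at -0.61 and Dnajb11 at -0.59, but 5 members, named after their values were seen, were at least 2-fold higher (Trib3 at 1.45, Chac1 at 1.27, Phgdh at 1.25, Atf3 at 1.18 and Asns at 1.06), and the list's mean of -0.01 did not stand apart (percentile 42.6). Genes of glucose production and use had a median of -0.17 over 26 genes (percentile 0.18), with the pyruvate kinase gene Pklr 2.29-fold lower, Got1 2.19-fold, Pfkfb1 1.84-fold and Sds 1.66-fold lower. Of these 26 genes, 2 were at least 2-fold lower and 2 at least 2-fold higher, and the list's mean of -0.14 did not stand apart (percentile 4.41). Amino acid breakdown and urea cycle genes lay at the edge (median -0.11 over 29 genes, percentile 2.49), with Acmsd at -1.76 and Aass at -0.74, and members of no other list had a median of -0.02, well within the random range (percentile 40.9). Circadian clock genes had a median of -0.31 over 17 genes (percentile 0.03) and a mean of -0.20 that did not stand apart (percentile 10.8); Usp2 differed by -1.64, Per1 by -0.60, Cry1 by -0.52 and Per2 by -0.42. Cytosolic ribosomal protein genes differed by a small median of -0.09 over 73 genes, 53 of them below 0 (percentile 2.08), with Rpl41 at -0.44, Rps26 at -0.40, Rps2 at -0.35 (its 4 probes reaching up to -0.16) and Rps29 at -0.33, and their mean, also -0.09, did not stand apart (percentile 4.93).

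Several other lists did not stand apart. Oxidative phosphorylation genes had a median of -0.04 over 71 genes (percentile 24.2), with Atp5hl1 at 0.64, Uqcrfs1 at 0.39 and Uqcr10 at -0.36. Methionine and one-carbon genes had a median of -0.07 over 20 genes (percentile 14.8), with Csad at 1.25, Bhmt at -0.91 (-1.70 by a second probe) and Gnmt at -0.67. Heat shock genes lay close to the upper limit (median 0.15 over 18 genes, percentile 97.3), with Hspb1 at 0.88, Hspb8 at 0.39 and Hspa1a at least 1.42-fold lower; they passed it with P on both arrays (percentile 97.8), in the series matrix (97.9) and by the mean (97.6) or median (97.7) of a gene's probes. Targets of p53 had a median of 0.06 over 23 genes (percentile 69.8), with Cdkn1a at -0.72, Plk2 at 0.51 and Bcl2l11 at least 1.22-fold higher. Immediate early genes, which respond to handling, had a median of 0.11 over 22 genes (percentile 85.9), with Egr3 at 1.35, Zfp36 at -1.01 and Fos at -0.74. Iron genes had a median of 0.01 over 20 genes (percentile 51.0), with the hepcidin gene Hamp at 0.73, Hpx at -0.66 and Smad7 at -0.49. The mean took the other sign from the median for lipoprotein (0.07), cytokine (-0.03), class II (-0.07) and iron genes (-0.01), as it did for ethanol metabolism (-0.37), the growth hormone and IGF axis (0.26) and adipocyte genes (0.23).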

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

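Probes without a gene symbol lie outside the comparison of genes, and 158 of the 8892 detected on both arrays were at least 2-fold above the saline array, with 236 at least 2-fold below it. The largest excess over the saline array was 3.92 log2 units (7.76 against 3.84). As a share, 4.43% of these probes were at least 2-fold apart, beside 4.00% of probes with a symbol. Of the tests weighed below, the one on the trend with signal was fixed before its result was seen; the others were chosen after the results were seen.

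Acute phase and complement genes were lower in the propolis pool, and Lcn2 stood out among them. The list's median could not rest on Lcn2 alone, since 30 of 34 members lay below 0, so only its mean was in question. Lcn2 alone carrying that mean is argued against by the mean of the other members, -0.44, at percentile 0.01 of random lists. Whether the Lcn2 value itself comes from a misread spot stays open, since 1 Lcn2 probe is on the array. An acute phase response in a few animals of the saline pool cannot be told apart from one in most of them, with 1 pool per group. An effect of the propolis extract on the hepatic acute phase, or of the ethanol it was given in, also stays open, and neither was tested separately.

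Kupffer cell markers were lower too. Less blood in the propolis livers as the whole cause is argued against by 7 measured markers of resident Kupffer cells, which blood holds little of: all 7 were below 0, with a median of -0.67 (percentile 0.01). These 7 belong to the same list, in which 15 of 16 genes were already seen below 0. Their count below 0 was thus nearly fixed and is no separate evidence. Cd163, among the markers chosen, was at only -0.11 by a second probe. A smaller share of all non-hepatocytes as the whole cause is argued against, for endothelial and stellate cells only, by the median of Kupffer markers minus that of endothelial and stellate markers. It was -0.45, at percentile 0 of matched random pairs, which treat genes singly. Other non-hepatocyte lists were not in this test. T and NK cell (-0.41), erythroid (-0.82), platelet (-0.55) and neutrophil genes (-0.58) were lower too. Cholangiocyte (-0.01) and B and plasma cell genes (0.11) did not stand apart. Fewer Kupffer cells and a lower expression of these genes per cell both stay open, and no value here separates them, nor an effect of the propolis extract from one of its ethanol vehicle or a difference between the pools. For erythroid genes, which were lower as well, less blood was not excluded.

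Drug metabolism and conjugation genes were mostly higher. A trend of the difference with signal is argued against as the whole cause by its size. Loess centring moved no difference by more than 0.0718, less than the smallest median of the 3 lists. After centring that median was 0.25 (percentile 100), but so small a move could not have brought it into the random range. More pericentral tissue in the propolis pool stays open: 12 pericentral markers outside the drug lists had a median of 0.26 (percentile 99.3; 0.13 and percentile 81.5 for markers of no other list), and the drug lists exceeded them by only 0.13, within the range of random pairs (percentile 91.3). The ethanol in which the extract was given cannot be told apart from the extract, because 0 groups received the ethanol vehicle without it. Induction by the propolis extract is open in the same way.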

How the results depend on the processing

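The alternatives that use members of no other list, one-array genes at their bound, acute phase genes without Lcn2, list means without 1 or 2 extreme members and genes with agreeing probes were chosen after seeing the data; the others were planned. Centring on the median of each array moved nothing, and repeated quantile normalization moved differences by at most 0.0184, so neither says anything about stability; loess centring moved them by at most 0.0718. Background correction by normexp was not run, as it needs scanner columns that were not used here. No paired analysis was possible because each group has 1 array. Of 24 lists that stood apart, 15 stayed on their side under every alternative run, and of 22 that did not, 16 stayed within the random range. Genes at least 2-fold higher, lower and in all numbered 192, 295 and 487 with only probes that had P on both arrays, 195, 297 and 492 in the series matrix, 129, 164 and 293 with 50 signal units added, 963, 1218 and 2181 at 1.5-fold, 206, 287 and 493 at 3-fold, and 12, 13 and 25 among 2596 genes whose probes, 2 or more, all passed; without a filter 663 were higher and 1566 in all. These counts differ by construction, through the genes that enter, the threshold or the shrinking of folds at low signal. The counts with agreeing probes are also low because probes of the same gene disagreed. Of 54 genes at least 2-fold apart by the brightest probe, 26 had a second probe also at least 2-fold apart on the same side. By the mean of members, lists that no longer stood apart were glucose genes (-0.14), ribosomal proteins (-0.087), unfolded protein genes (-0.013), clock genes (-0.20) and T and NK cells (-0.36). Without a filter they were extracellular matrix (-0.075) and neutrophil genes (-0.055). Amino acid genes joined the random range with P on both arrays (-0.11) and unmatched random lists (-0.11). With members of no other list, amino acid genes (-0.016), extracellular matrix (-0.13), pericentral (0.13) and neutrophil genes (-0.12) no longer stood apart. Lists that stood apart only under an alternative, on the same side, were fatty acid synthesis (-0.43) by the mean, muscle (-0.42) against unmatched lists, heat shock genes under 4 alternatives and ethanol metabolism under 5. Signs turned, to a side where the list stood apart, for ethanol metabolism (-0.37) and the growth hormone axis (0.26) by the mean and for stellate cells (0.16) without a filter. Among 206 named genes, 185 moved by less than the spread between probes throughout. That count says little about stability. A gene with 1 detected probe could not move by the mean or median of probes, and rescaling moved differences by at most 0.0718. Of the named genes at least 2-fold apart, 2 turned sign. Cela1 did so by the probe with the median difference (-0.24), here the lower of its 2 probes, and Top2a with P on both arrays or in the series matrix (0.21). Of the other named genes, Myh11 turned by the mean of probes (0.44). Beyond what construction explains, the cause was not tested. Low signal over background limits genes near 4 log2 units most.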

Other observations

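The tests of hypotheses in this part were chosen after the results were seen. Sex-biased liver genes differed in opposite directions, although all animals were male. Genes known to be higher in male rat liver were higher in the propolis pool (12 of 14 above 0, median 0.37, percentile 99.98), with Cyp3a2 at 1.13, Ces2h at 0.91, the urinary protein gene Mup4 at 0.88 and Obp3 at 0.86. Genes known to be higher in females were lower (7 of 9 measured below 0, median -1.12, percentile 0), with Adh6 at least 111-fold, Akr1b7 at least 4.09-fold and Cux2 at least 1.90-fold lower and Cyp2c12 at -1.42. Sult1c2 went the other way at 2.13. With genes detected on both arrays only, the female-biased median was -0.53 (percentile 0.06), and with the others at their bound -0.93 (percentile 0). The growth hormone and IGF axis did not stand apart by its median (-0.14 over 16 genes, percentile 3.81), and its mean of 0.26 stood apart on the other side (percentile 98.4), but not without Onecut1 (0.06, percentile 70.3). It held Onecut1 (3.21), Bcl6, a repressor of female-biased genes in male liver (-2.16, and -2.09 by a second probe), and Socs2 (2.06).

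Other lists stand for tissues that can be carried along in dissection. Pancreatic acinar genes had a median of 0.13 over 8 genes (percentile 78.8), with Cela1 at 1.99 by its brightest probe and -0.24 by another, Pla2g1b at -1.41 and Spink1 at -1.27 by its brightest probe and 0.10 by another. Adipocyte genes had a median of -0.04 over 7 genes (percentile 32.6) and a mean of 0.23, with Cidea at 1.10, Car3 at 0.88 and Pparg at 0.45. Muscle genes had a median of -0.42 over 5 genes (percentile 3.45), with Tnnc2 at least 2.81-fold lower, Tnni2 at -1.33 and Myh11 at -0.42; the second Myh11 probe lay at 1.29, and with the mean of probes the list's median was 0.19 (percentile 82.3). All 4 measured mesothelial genes lay below 0, with Msln at -2.23, Krt19 at -0.66 and Upk1b at least 7.81-fold lower. Kidney and adrenal genes (4 measured) included Cyp11b2 at least 2.58-fold higher, Cyp17a1 at -0.80 and Lrp2 at 0.48. Olfactory receptor genes, a background list, had a median of 0.14 over 21 genes (percentile 81.3), with Olr36 at least 2.93-fold and Olr1720 at least 2.93-fold higher and Olr1057 at least 2.78-fold lower.

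Higher fatty acid oxidation genes beside lower Scd and Fasn would also be seen after a longer fast of the animals in the propolis pool. That hypothesis is argued against as the whole cause by the cholesterol synthesis genes, which a fast lowers and whose median was 0.38 here.

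A probe without a symbol, described in the file as a vitamin D-binding protein sequence, had 1 of the largest negative differences, -4.63 (7.00 against 11.63). Reading of the vitamin D-binding protein gene Gc is argued against, since the Gc probe on chromosome 14 differed by 0.35 and another probe of that gene by -0.33. In the deposited coordinates, of a build not given in the sources used here, the unnamed probe lies on chromosome 1 from 97288372 to 97288431, 8104 base pairs from the nearest probe of the serum amyloid gene Saa4, which differed by -0.88; the other Saa4 probe, farther away, differed by -0.36. In GRCr8, Saa3 neighbours Saa4. The probe may therefore read an acute phase transcript of that locus; no sequence was available to test this, and the hypothesis stays open.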
